A study of Mus musculus with 35 samples.

How the data were processed

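The series covers cultured mouse neural progenitor cells (NPCs) that were wild type (WT), heterozygous (Het) or homozygous knockout (KO) for Mettl14, which encodes a subunit of the methyltransferase that places N6-methyladenosine (m6A) on messenger RNA. The labels list 35 samples. They comprise 19 RNA-seq libraries in 3 batches, 2 m6A immunoprecipitates (IP) and 2 inputs of methylated-RNA sequencing (meRIP-seq) in WT cells, and chromatin immunoprecipitation (ChIP) of histone H3 acetylated (H3K27ac) or trimethylated (H3K27me3) at lysine 27, with inputs, in 2 WT and 2 KO lines.

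The deposited RNA tables give, per the file headers, raw fragment numbers for each locus and library, which are estimated counts: 5.31% of the batch 1 values and 2.31% of the batch 3 values were not whole numbers within a tolerance of 1e-9. The same deposited tables give FPKM, fragments scaled to transcript length and library size, which the authors scaled between libraries. Per the submitters' processing notes the tools were TopHat2 2.1.0, TopHat, Cufflinks and Cuffdiff on genome build mm10, in roles and an order that the notes do not give. Loci come from the authors' merged assemblies, one per batch. The batch 1 table has 32572 loci, of which 8847 carry no known gene name and 429 join more than 1 known gene, and the batch 3 table has 26458, 2716 and 305. A locus that joins genes gives them 1 shared value. Loci with the status HIDATA (2 and 1) were left out, and those with the status FAIL (190 and 36) were kept. The table for batch 2 is byte for byte the same as the table for batch 1, and the 6 RNA libraries of batch 2 were not analysed here. The 13 libraries used are 3 WT, 3 Het and 3 KO of batch 1 and 2 WT and 2 KO of batch 3. The tables number libraries within a group but do not tie them to culture lines, so a single library is named here by its group only.

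The meRIP-seq and ChIP peaks were called per the submitters' processing notes with Bowtie2 2.3.1 and MACS2 on mm10. By the names of the deposited m6A lists, each sets 1 IP against 1 input, so that the 4 lists combine the 2 IPs with both inputs, and each ChIP list sets 1 line against its own input. Per the file headers and format, each peak has a fold enrichment over input (a ratio), a −log10 p, a −log10 q and a score. The deposited score is the −log10 q times 10, and no peak had a −log10 q under 1. The files hold no read depth for these assays, so the depth behind a peak is unknown.

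Fragment numbers were rounded and summed over loci of 1 symbol, and loci without a known gene were left out of the gene tests. Each batch was fitted alone, and 23004 gene keys shared by the 2 tables were fitted over batches with batch as a covariate. The fits used edgeR 4.0.16 with TMM scaling (factors 0.969 to 1.04), its default low-count filter and the robust quasi-likelihood F test, which is two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. All adjusted p-values of single genes given here are from this edgeR test unless another tool is named. There were 13514 genes tested over batches, 13672 in batch 1 and 12835 in batch 3. CPM are counts scaled to library size with the TMM factors, given as mean ± SD. Log2 fold changes carry a standard error (SE), the log2 fold change divided by the square root of F. A fold against a group whose libraries were all at 0 was computed against a floor of 3 counts per library. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. With 14.1 to 20.0 M fragments per library, tests on simulated counts with the fitted dispersions recovered 58% of genes changed 1.5-fold and 88% of those changed 2-fold for KO against WT over batches, 44% and 88% for Het against WT, and 20% and 58% in batch 3 alone, with 50 changed genes at each fold. Each simulation changed 200 genes in all. Recovery depends on the number of genes changed, so these shares need not hold where far more or far fewer genes change.

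The 32 gene lists were fixed before the data were examined, as were the tests, the alternatives, the naming rule and the predictions of the closing section. They cover m6A factors, S phase, G2 and M phase, CDK inhibitors, neural stem cells, proneural genes, neuronal differentiation, GABAergic, dorsal telencephalic, astrocyte and oligodendrocyte genes, the Notch, Hedgehog and Wnt pathways, histone acetylation, Polycomb and H3K4 enzymes, Hox genes, p53 targets, interferon, stress, hypoxia and glycolysis, cholesterol, immediate early and imprinted genes. They also cover markers of microglia, endothelium, fibroblasts, erythroid cells and choroid plexus, sex-linked transcripts and mitochondrially encoded transcripts. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, each adjusted by Benjamini-Hochberg over the lists. Members called were counted over all genes tested and adjusted over the list alone. Named genes are Mettl14, Crebbp and Ep300, and for KO against WT over batches the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, a locus of 1 known gene, and every KO library above or below every WT library in each batch. For Het the same rule took up to 5 in each direction. From each list come up to 4 called members with the smallest p, or 2 where none was called, and from each mark the 5 promoters gained and the 5 lost with the highest mean CPM in batch 3. Predicted and ribosomal genes are not named, and some genes that the rule selects are not reported here. Other genes named are stated to have been chosen after their values were seen.

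Intervals were compared with bedtools 2.31.1, any overlap of at least 1 bp counting as shared. Genes were called m6A-marked when a peak of each of the 4 lists overlapped their exons. Their RNA change was tested with camera and against 10000 random lists matched on mean expression (20 bins), or on expression and transcript length (10 by 10 bins). Promoters were the 1 kb on either side of every transcript start of 23906 genes in the deposited assembly. They are counted per gene, and a gene's promoter had a peak where any of its starts had one. A promoter peak present in both KO lines and in neither WT line was called gained, and the reverse lost. The 4 lines can be split into pairs in 3 ways, so no p below 0.33 is possible for a difference between genotypes in peaks. Promoter sets were tested with camera in both RNA batches, adjusted over 8 tests.

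Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, a 1.5-fold threshold, limma on log2 FPKM with pseudocounts of 1 or 0.1, loci with several genes or the sex chromosomes left out, each library, line or batch left out, only the compared genotypes in the fit, peaks with a −log10 q of at least 5, equal numbers of top peaks, a 50% reciprocal overlap, a window of 2.5 kb, and 500 bp of the window covered. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.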

Results

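RNA was profiled in neural progenitor cultures of 3 Mettl14 genotypes, m6A was mapped in WT cultures, and 2 histone marks were mapped in WT and KO lines. In batch 1 there were 3 WT, 3 Het and 3 KO libraries, and in batch 3 there were 2 WT and 2 KO libraries. On a multidimensional scaling plot the first axis (59.6% of the variance) separated the batches. The second (22.7%) placed every KO library above 0 and every WT and Het library below 0. Transcripts of the Y-linked genes Uty, Kdm5d and Eif2s3y were present in some libraries and absent from others of each group, so the libraries of each group were mixed in this respect.

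The first comparison asked how RNA levels differ when Mettl14 is lost. Cells without Mettl14 had far less RNA of the matrix gene Tnc and the cyclin gene Ccnd1, and more RNA of Gad1, Apoe and several genes that WT progenitors barely expressed. Tnc, which encodes tenascin C, fell from 2170 ± 170 to 226 ± 8.3 CPM in batch 1 (n = 3 and 3) and from 1760 ± 140 to 332 ± 1.7 in batch 3 (n = 2 and 2). Ccnd1, the cyclin of G1 entry, fell from 1910 ± 120 to 163 ± 21 and from 2120 ± 380 to 622 ± 110 CPM. Gad1, which makes the transmitter GABA, rose from 4.05 ± 1.5 to 81.7 ± 12 and from 3.57 ± 0.12 to 85.5 ± 1.0 CPM. Over both batches 8594 of 13514 genes were called, 4433 higher and 4161 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg). The balance turned with limma on FPKM, to 3441 higher and 4306 lower. Of the genes called by edgeR, 2600 higher and 2567 lower ones met every criterion of the naming rule, including no overlap between KO and WT libraries in either batch. Chance alone gives such a separation in the same direction in both batches for 1.7% of genes, and in batch 1 alone for 10%.

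**Figure D1:**
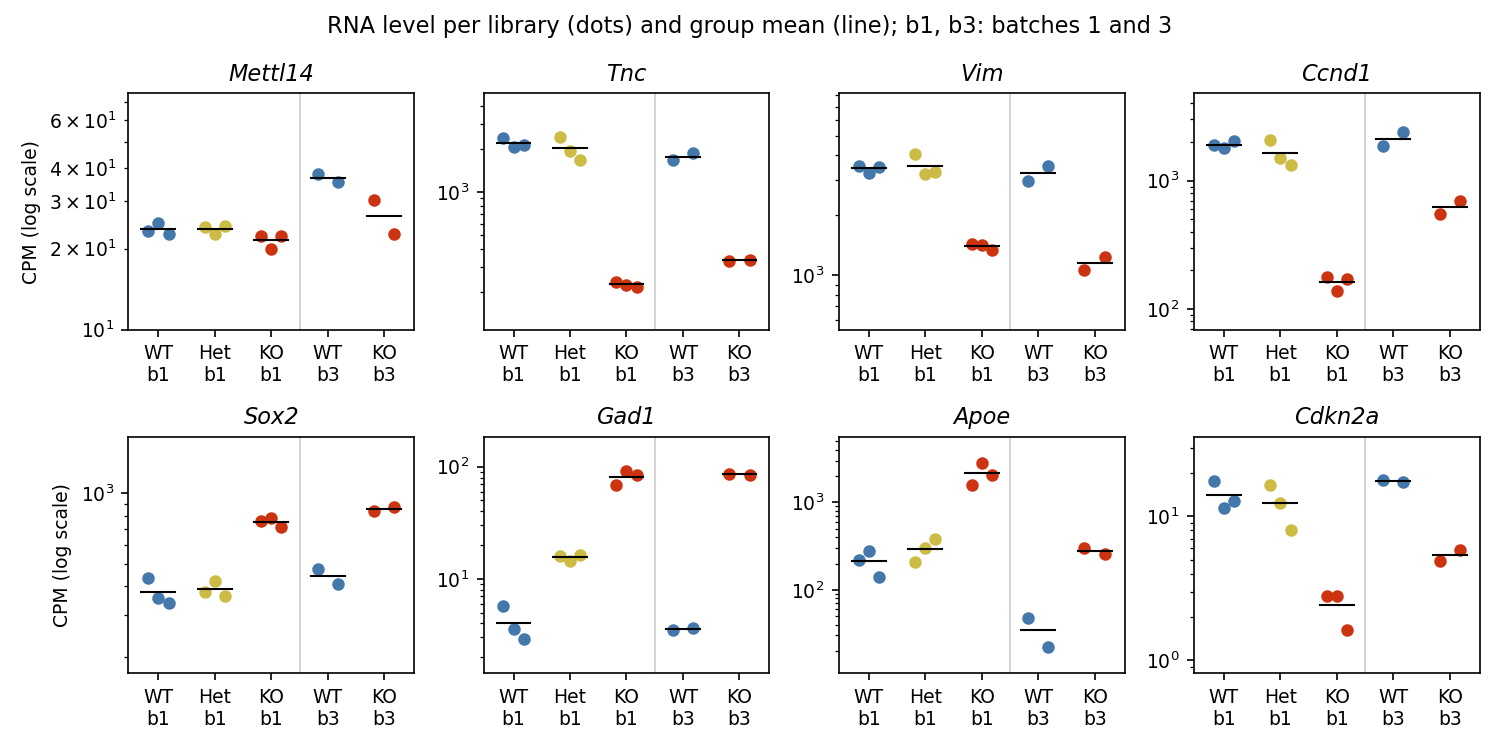
RNA level in CPM (log axis) of 8 genes, 1 dot per library and a line at each group's mean, for WT, Het and KO of batch 1 and WT and KO of batch 3. Gad1 averaged 81.7 and 85.5 CPM in KO against 4.05 and 3.57 in WT, with Het between at 15.7, whereas Mettl14 itself differed little.

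Mettl14 (chromosome 3, 123368295 to 123385990, mm10) showed a small loss of RNA over its whole locus, with a log2 fold change of −0.24 (SE 0.099, adjusted p = 0.048). Its level was 23.6 ± 1.2 CPM in WT and 21.6 ± 1.4 in KO of batch 1 (n = 3 and 3), and 36.6 ± 1.7 and 26.5 ± 5.4 in batch 3 (n = 2 and 2). In neither batch fitted alone did it pass the test (adjusted p = 0.22 and 0.084), whereas the fit with an interaction term called the fall in batch 3 (−0.47, adjusted p = 0.01) and not in batch 1 (adjusted p = 0.51). The labels describe loxP sites around exon 2, and the locus count includes exons outside the deleted part, so it does not measure the deletion.

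Among the largest rises were the olfactory receptor gene Olfr1351 (chromosome 10, 79017324 to 79018283; log2 fold change 8.57, SE 0.23) and Tg, which encodes thyroglobulin (chromosome 15, 66670770 to 66850720). Olfr1351 was at 130 ± 4.2 CPM in KO and 0.339 ± 0.2 in WT of batch 1, and fell below the low-count filter of the batch 3 fit. The fit with an interaction term called its rise in batch 3 as well (edgeR adjusted p = 0.00083), where no WT fragment was counted. Tg was at 27.8 ± 1.5 against 0.213 ± 0.13 CPM in batch 1. In batch 3 its KO level was 11.5 ± 4.1 CPM and no fragment was counted in either WT library, which makes it at least 58-fold higher against a floor of 3 counts per library. Ahnak had a log2 fold change of 5.17 (SE 0.50) and Gad1 (chromosome 2, 70562164 to 70602012) one of 4.46 (SE 0.16, adjusted p = 1.6e-09). Others were Srcin1 (4.13), the T-type calcium channel gene Cacna1g (4.06), Rassf10 (3.85) and the protease inhibitor gene Serpina3n (3.84). Rassf10 was below the filter of the batch 3 fit and was not called there with an interaction term (1.96, adjusted p = 0.084). By the same term the rise of Srcin1 differed between batches (5.11 in batch 1 and 2.72 in batch 3, adjusted p = 0.024).

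The largest falls removed nearly all RNA of genes that WT cells expressed. Fam135b (chromosome 15, 71439972 to 71728061) went from 37.8 ± 13 to 0.122 ± 0.062 CPM in batch 1 and from 37.1 ± 8.3 to 0.424 ± 0.13 in batch 3, a log2 fold change of −7.22 (SE 0.31, adjusted p = 5.4e-09). Anxa3, an annexin gene (chromosome 5, 96793385 to 96845968), went from 65.1 ± 27 to 0.113 ± 0.085 and from 62.5 ± 1.7 to 2.05 ± 0.92 CPM (log2 fold change −6.26, SE 0.50). Dhh, the Desert hedgehog ligand, had a log2 fold change of −5.39 and Thbd, encoding thrombomodulin, one of −5.75. Pcp4l1 (−5.56), the bradykinin receptor gene Bdkrb2 (−5.15), AI593442 (−5.14), the adhesion receptor gene Gpr98 (−4.90), Golga7b (−4.86) and the cadherin gene Cdh19 (−4.68) completed the set. By an interaction term the fall was larger in batch 1 than in batch 3 for Golga7b (−6.23 and −3.39, adjusted p = 0.0066), Dhh (−7.29 and −4.22, 0.0091) and Anxa3 (−8.98 and −4.91, 0.01).

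Genes of the cell cycle fell together. Of 23 measured S phase genes, 21 fell and none rose (median log2 fold change −1.42), among them the cyclin Ccne2 (−2.16, SE 0.33), the DNA polymerase gene Pola1 (−1.49, SE 0.16), Slbp (−1.24) and the thymidylate synthase gene Tyms (−0.74). Of 19 measured G2 and M phase genes 18 fell and none rose (median −0.90), including the topoisomerase gene Top2a (−1.23), the cyclin Ccna2 (−1.23), Hmmr (−1.27) and the spindle checkpoint gene Bub1b (−0.60). By an interaction term the fall was larger in batch 1 than in batch 3 for Slbp (−1.67 and −0.62, adjusted p = 0.0025), Ccne2 (−3.01 and −1.07, 0.0036), Pola1 (−1.84 and −0.97, 0.011) and Ccna2 (−1.56 and −0.74, 0.031). Tyms, Top2a, Hmmr and Bub1b did not pass that test. Adjusted over the list alone, 22 and 19 members of the S phase and the G2 and M phase lists fell. Camera called both lists lower (adjusted p = 1.3e-05 and 2.3e-05), and each was also called in batch 1 alone (2e-11 and 0.00011) and in batch 3 alone (7.6e-05 and 6.5e-05). Neither call held with an estimated correlation (adjusted p = 0.6 with an estimated correlation for each), where members' inter-gene correlations were 0.92 and 0.83.

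The inhibitors of cyclin-dependent kinases did not rise as a group. Of 7 measured, Cdkn2a (−2.15, SE 0.24), Cdkn2b (−1.53) and Cdkn1a (−1.23) fell and Cdkn2d rose (0.32, SE 0.13; 0.04 in batch 1 alone, adjusted p = 0.75; difference between batches, adjusted p = 0.047), with an adjusted p of 0.15 for the list. Of 20 targets of the tumour suppressor p53, 13 fell and 2 rose (median −0.42, adjusted p = 0.0029; adjusted p = 0.6 with an estimated correlation). They included Cdkn1a, Ccng1 (−0.93), the pro-apoptotic gene Pmaip1 (−1.22) and Zmat3 (−0.49). This list was called in batch 1 alone (adjusted p = 7e-04) and not in batch 3 alone (0.09). Of 15 hypoxia and glycolysis genes, 9 fell and 1 rose (median −1.17, adjusted p = 0.046; adjusted p = 0.79 with an estimated correlation), among them the glycolytic enzyme genes Pfkp (−1.95), Eno1 (−1.73), Pgk1 (−1.32) and Aldoa (−1.19). Aldoa did not pass in batch 3 alone (−0.60, adjusted p = 0.062) but did with an interaction term (adjusted p = 0.014), and its effect differed between batches (adjusted p = 0.015). The falls of Pgk1 (−1.73 in batch 1 and −0.70 in batch 3, adjusted p = 0.0067), Eno1 (−2.24 and −0.97, 0.0076), Pfkp (−2.37 and −1.33, 0.024) and Cdkn1a (−1.44 and −0.93, 0.037) differed between batches too. The adjusted p of the list was 0.00018 in batch 1 alone and 0.43 in batch 3 alone.

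Markers of neural identity moved apart within their lists, and no such list was called by camera. Of 21 neural stem cell and radial glia genes 8 fell and 7 rose (adjusted p = 0.3): besides Tnc (−2.90), the intermediate filament gene Vim (−1.35) and Prom1 (−1.80) fell, whereas the progenitor transcription factor Sox2 rose (1.00, SE 0.081). Of 14 proneural genes 10 rose and 1 fell (0.42), with Neurog2 (5.00, SE 0.53), Neurod4 (1.71) and Sstr2 (1.69), with KO means of 12.2, 2.37 and 1.37 CPM in batch 1, against the Notch ligand Dll3 (−1.85). In the fit with an interaction term Neurog2 was called in batch 3 (3.49, SE 1.1, adjusted p = 0.021), and Neurod4 (0.42, adjusted p = 0.6) and Sstr2 (0.32, adjusted p = 0.84) were not. The list leaned down in batch 3 alone (0.75). Of 19 neuronal differentiation genes 3 rose and 8 fell (0.66): the cell adhesion gene Ncam1 (0.82) rose, while the neurofilament genes Nefm (−2.26) and Ina (−1.90) fell. Of 14 astrocyte genes 9 rose and 4 fell (0.59), with Apoe (3.23, SE 0.27) and the glutamate transporter Slc1a2 (1.45) against Aldh1l1 (−2.10) and Cd44 (−1.19). Of 11 oligodendrocyte genes 3 rose, including the myelin genes Mog (2.83) and Cnp (1.00), and 4 fell, including Cspg4 (−1.21), at an adjusted p of 0.94. Among 7 GABAergic genes 2 rose, including Gad1, and none fell (0.21). Among 8 dorsal telencephalic genes 5 rose, including Lhx2 (0.62), and Pax6 fell (−0.58), at an adjusted p of 0.39, and this list too leaned down in batch 3 alone (0.75). Of the genes named here, Ncam1 (0.28, adjusted p = 0.29), Cnp (0.56, adjusted p = 0.05) and Lhx2 (0.31, adjusted p = 0.23) did not pass in batch 3 alone, and the effect on Ncam1 differed between batches (adjusted p = 0.022). So did the falls of Pax6 (−0.27 in batch 1 and −1.03 in batch 3, adjusted p = 0.0053) and Tnc (−3.23 and −2.41, adjusted p = 0.012). Mog, Nefm and Ina had low RNA levels, with means over all libraries of 2.32, 2.85 and 2.25 CPM.

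**Figure D2:**
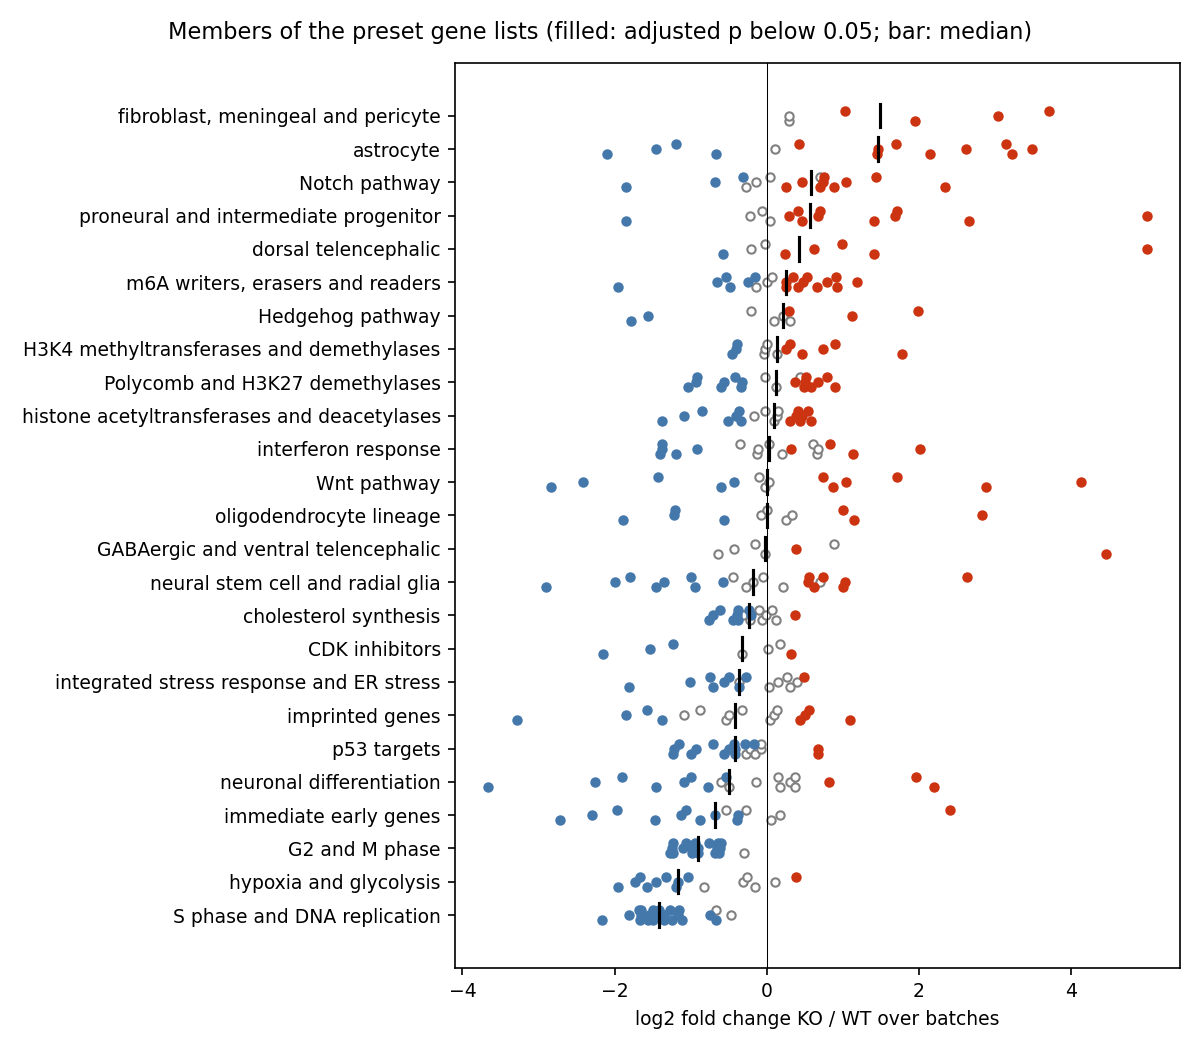
Log2 fold change of KO against WT over batches for each measured member of the gene lists with at least 5 measured genes, filled where the adjusted p was below 0.05, with a bar at the list's median. The list of sex-linked transcripts is left out. The S phase list (median −1.42) and the G2 and M phase list (median −0.90) had no member that rose.

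Enzymes of m6A and of histone modification had members in both directions, and none of their lists was called. Of 20 m6A factors 11 rose and 6 fell (adjusted p = 0.16), among them the readers Ythdf2 (1.19, SE 0.06), Ythdf1 (0.91) and Ythdc1 (0.66) and the writer component Rbm15b (0.93). Of 19 histone acetyltransferases and deacetylases 7 rose and 7 fell (0.39). The acetyltransferase genes Crebbp (0.55, SE 0.097, adjusted p = 0.00026) and Ep300 (0.44, SE 0.096, adjusted p = 0.0013) rose, and the deacetylase genes Hdac1 (−1.09), Hdac9 (−1.38), Hdac5 (−0.85) and the acetyltransferase Kat7 (−0.40) fell. In batch 3 alone Crebbp (0.39), Ep300 (0.24) and Kat7 (−0.34) did not pass (adjusted p = 0.13, 0.35 and 0.068). With an interaction term Crebbp and Kat7 were called there (adjusted p = 0.036 and 0.0016) and Ep300 was not (0.15). Of 19 Polycomb genes and H3K27 demethylases 8 rose and 8 fell (0.79), including the core subunit Eed (−0.93), Rbbp7 (−1.04) and Rbbp4 (−0.56), all lower. Of 13 H3K4 enzymes 6 rose, including Setd1b (1.78), Kmt2b (0.90) and Kdm5b (0.74), and 3 fell, including Ash2l (−0.45), at 0.39. The effect differed in size between batches, with the same sign, for Rbbp7 (−1.31 in batch 1 and −0.63 in batch 3, interaction adjusted p = 0.012), Ythdf1 (0.75 and 1.16, 0.024) and Hdac9 (−1.15 and −1.75, 0.03).

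Signalling and stress lists also contained members in both directions. For Notch 9 of 16 rose and 3 fell (adjusted p = 0.39), with Hey2 (2.35) and Maml1 (0.76) up and Lfng (−0.68) down. The list was called higher in batch 1 alone (adjusted p = 0.019) and not in batch 3 alone (0.78), and over batches had an adjusted p = 0.87 with an estimated correlation. For Hedgehog 3 of 9 rose, with Gli2 (1.99) and Boc (1.12), and 2 fell, Cdon (−1.56) and Hhip (−1.79), at 0.94. For Wnt 6 of 14 rose, with Apcdd1 (2.88) and Nkd1 (1.71), and 5 fell, with Ccnd1 (−2.83) and Sfrp2 (−2.41), at 0.94. The interferon list had 4 up and 5 down of 17 (0.72), with Bst2 (−1.37), Ifih1 (−1.37), Gbp3 (−1.19) and Ifit2 (−0.92) lower. The integrated stress response list had 1 up and 8 down of 15 (0.23), with Asns (−1.81), Atf5 (−1.01), Xbp1 (−0.71) and Sesn2 (−0.56) lower. The cholesterol list had 1 up and 9 down of 17 (0.24), with Idi1 (−0.71) lower and Fdft1 (0.37) higher. Both were called lower in batch 1 alone (adjusted p = 0.045 and 0.018), and over batches had an adjusted p = 0.6 and adjusted p = 0.87 with an estimated correlation. In batch 3 alone the cholesterol list leaned up (0.75). Of 15 immediate early genes 1 rose and 10 fell (0.14), with Arc (−2.30), Ier3 (−1.97) and Ier2 (−1.13) lower and Fosl1 (2.41) higher, and this list was called lower in batch 3 alone (adjusted p = 6.5e-05; over batches adjusted p = 0.6 with an estimated correlation). Of 16 imprinted genes 4 rose, including Zrsr1 (1.09) and Impact (0.56), and 4 fell, including Mest (−3.28) and Grb10 (−1.85), at 0.39. Of the genes of this paragraph, Boc (0.42, adjusted p = 0.19), Bst2 (−1.21, 0.052), Gbp3 (−0.45, 0.09), Ifit2 (−0.57, 0.093), Sesn2 (−0.27, 0.15) and Idi1 (−0.22, 0.27) did not pass in batch 3 alone, and Fdft1 (0.17, 0.058) did not in batch 1 alone. With an interaction term Bst2 was called in batch 3 (adjusted p = 0.022) and Fdft1 in batch 1 (0.036), and Fosl1, below the filter of the batch 3 fit, was not called there (2.13, 0.091). The effect differed between batches for Boc (adjusted p = 0.0049), Gbp3 (0.03), Sesn2 (0.029), Idi1 (0.0034) and Fdft1 (0.043). It also differed in size, with the same sign in both batches, for Ccnd1 (−3.51 in batch 1 and −1.77 in batch 3, adjusted p = 0.0018), Asns (−2.39 and −0.96, 0.0021), Ier2 (−0.63 and −1.88, 0.013), Mest (0.02), Nkd1 (0.031) and Grb10 (0.048). RNA levels were low for Fosl1 (mean over all libraries 0.307 CPM), Ifih1 (1.98), Hey2 (2.97), Bst2 (4.39) and Hhip (4.73).

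Markers of other cell types were low. Of 12 fibroblast and pericyte markers 6 were measured and 4 rose, Col3a1 (3.04), Pdgfrb (3.72), Acta2 (1.95) and Tagln (1.03), each with a KO mean of 4.86 CPM or less in either batch (adjusted p = 0.24 for the list). Of 2 measured microglial markers P2ry12 fell (−0.91; list 0.7), of 3 endothelial markers Flt1 fell (−4.34; list 0.79), and of 2 choroid plexus markers Otx2 fell (−3.82, SE 0.43; list 0.37). Alas2, the 1 measured erythroid gene, had a log2 fold change of 0.58 (adjusted p = 0.054). None of 5 sex-linked transcripts was called (0.95), with Uty at −0.08 and Eif2s3y at 0.07. In batch 3 alone Tagln did not pass (1.41, adjusted p = 0.065; 0.0096 with an interaction term). Pdgfrb, P2ry12 and Flt1 were below the filter there, and with an interaction term Flt1 was called in batch 3 (adjusted p = 0.039) and Pdgfrb (0.33, adjusted p = 0.75) and P2ry12 (−0.91, adjusted p = 0.14) were not. The effect on Pdgfrb differed between batches (adjusted p = 0.0057). No Hox gene and no mitochondrially encoded transcript was measured. Median and test differed in sign for the GABAergic (median −0.02, mean 0.64, test up), Hedgehog (0.22, 0.05, down), acetylation (0.10, −0.08, down), Polycomb (0.12, 0.01, down), interferon (0.03, −0.02, down) and endothelial (0.34, −1.19, down) lists, none of them called. Counts adjusted over the list alone differed from the counts over all genes in 7 lists: besides the 2 cell cycle lists, there were 1 GABAergic, 4 oligodendrocyte, 2 interferon and 1 erythroid member higher and 8 acetylation members lower.

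Comparing the batches asked whether the KO effect recurs in other lines of another batch. In batch 1, 9463 of 13672 genes were called (4681 higher, 4782 lower; 3696 and 5124 with limma on FPKM), and in batch 3, 4073 of 12835 (2220 higher, 1853 lower). Among the 12401 genes tested in both, 1828 of the 4233 called higher in batch 1 were called higher in batch 3, where 728 were expected of independent lists, and 1561 of the 4573 called lower were called lower, where 662 were expected. Of the 3465 genes called in both, 97.8% had the same sign. The log2 fold changes correlated with a Pearson r of 0.757 and a Spearman rho of 0.718 across genes, which are not independent replicates. Among genes called in both, the slope of batch 3 on batch 1 was 0.79. The test of the difference itself found 2582 genes whose KO effect was not the same in the batches, of which 776 were called in both with 1 sign. Leaving out either WT library of batch 3 lowered the batch 3 count, and leaving out either KO library raised it. Each of these fits leaves 1 library in a group.

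**Figure D3:**
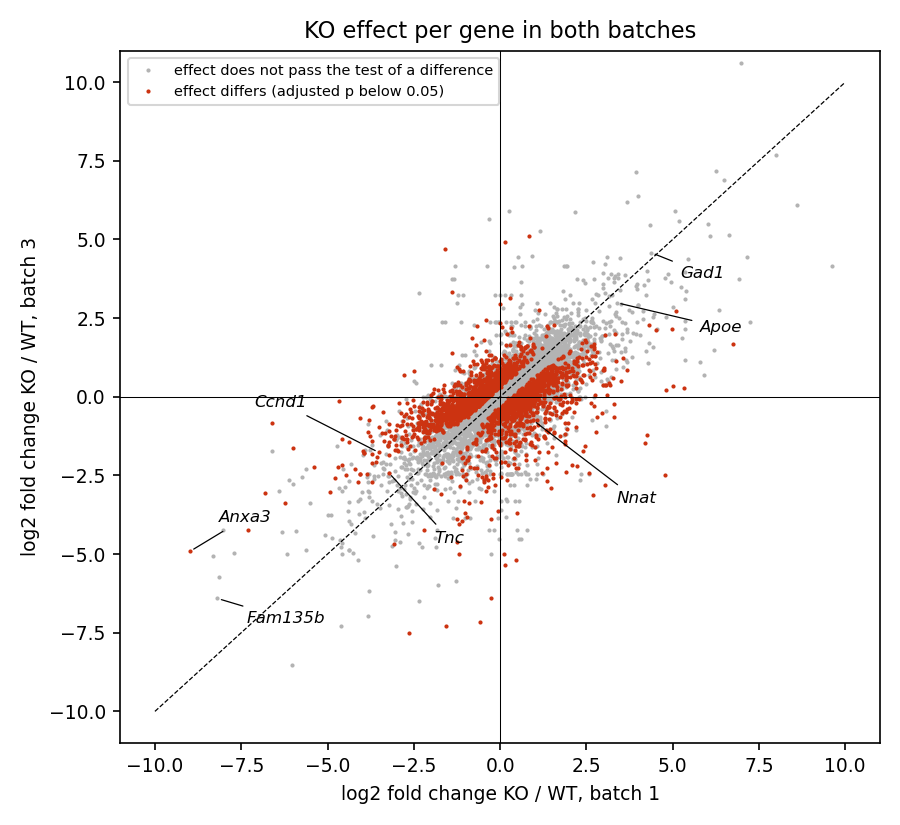
Log2 fold change of KO against WT per gene in batch 1 (x axis) and batch 3 (y axis), red where the effect differed between batches, with a dashed line at equality. Fam135b lay at −8.19 and −6.41 and Gad1 at 4.38 and 4.58, whereas Nnat lay at 0.95 and −0.74.

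The Het cultures asked whether losing 1 copy of Mettl14 changes RNA. Gad1 alone was called, at 15.7 ± 1.1 CPM in Het (n = 3) against 4.05 ± 1.5 in WT of batch 1 (n = 3), a log2 fold change of 2.01 (SE 0.18, adjusted p = 0.00044) and higher in 3 of 3 libraries than in any WT library. At an unadjusted p below 0.05 there were 507 genes of 13514, and DESeq2 called 6. As a share of genes, 507 is under the 0.05 expected on average with no difference. Leaving out 1 of the WT libraries of batch 1 raised the edgeR count to 3. Mettl14 itself had a log2 fold change of −0.07 (SE 0.12). In batch 1 alone edgeR called 2 genes, Gad1 (1.96, adjusted p = 0.028) and S100a16, which encodes a calcium-binding protein and is named after its values were seen (1.67, SE 0.19, adjusted p = 0.028; 16.2 to 19.7 CPM in Het and 4.98 to 6.25 in WT). DESeq2 called 25 there. At an unadjusted p below 0.05 there were 1173 genes of 13672 in batch 1 alone, a share above 0.05. Genes are not independent, so neither count by itself tells whether Het differs. Leaving out 1 of the WT libraries raised the count in batch 1 to 17 and leaving out any other library of the comparison lowered it to 0. KO and Het differed nearly as widely as KO and WT: 7862 genes were called, 4045 higher and 3817 lower in KO (2815 and 4177 with limma on FPKM), with Gad1 at 2.44 (SE 0.17), Tnc at −2.95 (SE 0.18), Fam135b at −7.12 (SE 0.34) and Sox2 at 0.97 (SE 0.10).

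In the Het comparison over batches camera called 4 lists. GABAergic (adjusted p = 3e-04; adjusted p = 0.42 with an estimated correlation), astrocyte (0.001; adjusted p = 0.72 with an estimated correlation) and hypoxia and glycolysis genes (0.00063; adjusted p = 0.81 with an estimated correlation) were higher. Immediate early genes were lower (0.0096; adjusted p = 0.72 with an estimated correlation). No member but Gad1 was called, and adjusted over the list alone 1 astrocyte gene was higher as well. The members with the smallest p were Aldh1l1 (0.70, SE 0.13) and Slc1a2 (0.51) in the astrocyte list, Bnip3 (0.45) and Vegfa (0.44) in the hypoxia list, and Egr2 (−1.08) and Arc (−0.77) among immediate early genes. All Het libraries used are of batch 1, and without batch 3 the GABAergic (adjusted p = 0.00031) and astrocyte (2.2e-05) lists were called and the hypoxia (0.32) and immediate early (0.24) lists were not, while S phase (0.049), stress response (0.0062) and cholesterol (0.0021) genes were called lower (over batches adjusted p = 0.89, adjusted p = 0.81 and adjusted p = 0.95 with an estimated correlation). The S phase list turned between these fits, leaning up over batches (median 0.12, adjusted p = 0.21). The fit over batches assumes 1 KO effect for both batches and holds no Het library of batch 3. A KO effect that differs between batches therefore shifts its Het estimates. The hypoxia and immediate early calls and the S phase turn cannot be told apart from such a shift. No other list was called over batches.

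The m6A map asked which transcripts carry the mark in WT progenitors. The 4 lists held 16747 to 18291 peaks with a median fold enrichment over input of 4.02 to 4.22, of which 77.0 to 81.9% lay on exons. Between lists that by their names shared neither IP nor input, 64.2 to 73.4% of peaks overlapped (mean 69.0%), and between lists from 1 IP 75.0 to 82.8%. There were 10892 regions covered in all 4 lists. On transcripts with several exons 57.2% of the regions lay in the last exon, which makes up 54.3% of the length of the same transcripts. Within that exon 57.8% of its regions lay in the first 25% of its length and 5.6% in the last 25%. Peaks of every list fell on exons of 5991 genes.

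Transcripts marked in WT cells had a higher median change in KO cells than other transcripts, but other splits of the libraries gave a p as small in 7 of 60 cases, the real split included; the one with the smallest p kept 2 of 3 KO libraries of batch 1 and 2 of 2 of batch 3 in place. Of 5697 m6A-marked genes tested, 2429 rose and 1496 fell with a median log2 fold change of 0.14 (quartiles −0.27 and 0.57), and of the 7817 other genes 2004 rose and 2665 fell with a median of −0.06 (quartiles −0.49 and 0.41). These other genes include some with a peak in part of the lists. Of the 4560 tested genes with a peak in no list, 1219 rose and 1366 fell, with a median of −0.01 (quartiles −0.48 and 0.53). By these counts genes with a peak in only part of the lists fell more often than they rose. They also fell more often than genes in no list, so they moved opposite to the genes marked in all 4 lists. Camera of the marked genes gave p = 0.00043, and p = 0.0063 with an estimated correlation. Of 10000 random lists matched on expression the central 95% had medians from −0.005 to 0.021, and none reached 0.14, so that the share was the smallest possible, 1e-04. With transcript length matched as well the range was 0.017 to 0.042. Any of the lists had a peak on 9495 genes, and the tested genes of this wider set did not pass camera at the preset correlation (p = 0.22).

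**Figure D4:**
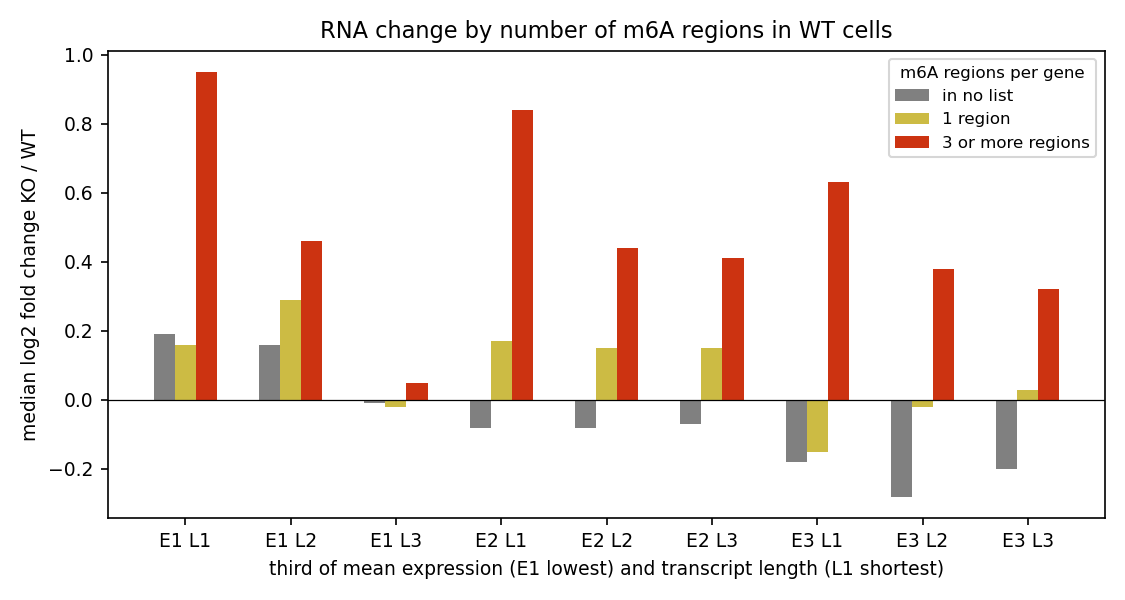
Median log2 fold change of KO against WT for genes with a peak in no m6A list, with 1 region or with 3 or more regions covered in all 4 lists, within 3 classes each of mean expression (E1 lowest) and transcript length (L1 shortest); bars rest on 6 to 1242 genes. In the 5 bins with at least 20 genes in each class the medians were 0.32 to 0.84 for 3 or more regions, −0.02 to 0.17 for 1 region and −0.28 to −0.07 for no list.

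Histone maps asked whether the active mark H3K27ac and the silencing mark H3K27me3 differ without Mettl14. H3K27ac, a mark of active promoters and enhancers, gave 55130 to 80947 peaks per line and lay on 56.7 to 61.3% of promoters. H3K27me3, the Polycomb mark of silent genes, gave 33188 to 59561 peaks and lay on 15.3 to 18.6% of promoters. Base-pair overlap (Jaccard index) of H3K27ac was 0.427 within and 0.391 between genotypes, the largest gap of the 3 splits of the lines (exact p = 0.33, the smallest possible). For H3K27me3 it was 0.349 within and 0.353 between, and another split, which set KO line 530 with WT line 541, had a larger gap (0.053).

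Promoters of Lrrtm4 (chromosome 6, 80018877 to 80024932), Gpr179, Sema6b, Tnip1 and Pdzk1 gained H3K27ac in both KO lines, among 107 gained and 264 lost of 23906. The other splits of the 4 lines gave 193 and 249 promoters in total against 371, and without KO line 530 the balance turned to 538 gained and 387 lost. With 1 KO line left, a gained promoter needs a peak in that line only, while a lost one still needs both WT lines. That turn can therefore come from the rule itself. Lrrtm4 (2.42, SE 0.29), Sema6b (1.79) and Gpr179 (1.32) rose in batch 3 RNA, and Tnip1 (0.23) and Pdzk1 (−0.42) did not pass. Of the most expressed genes that lost the mark, Psmc1 (−0.48) and Zfp385a (−0.50) fell in batch 3 RNA, Cd276 (0.65) and Ip6k2 (0.53) rose, and Mrpl45 (0.11) did not pass. H3K27me3 was gained at 241 promoters, among them Camk2b (chromosome 11, 5969666 to 6065748), Dclk1, Rcc2, Sox6 and Specc1, and lost at 165, among them Nkd1, Fam171a2, Zfp518b, Phc2 and Scoc. That total of 406 was below the 469 of the split that set KO line 530 with WT line 541, whereas with stricter peaks the genotypes had 146 and the other splits 37 and 47. The H3K27me3 balance turned without WT line 532 (370 gained, 413 lost) and without WT line 541 (402 and 595), and was even with equal numbers of top peaks (158 and 159). With 1 WT line left, a lost promoter needs a peak in that line only, while a gained one still needs both KO lines. The turn can therefore come from the rule itself. Camk2b, a subunit of a calcium-dependent kinase, fell from 393 ± 45 to 131 ± 7.2 CPM in batch 3 (n = 2 and 2) and from 354 ± 28 to 36.3 ± 16 in batch 1 (n = 3 and 3). Dclk1 (−0.69), Rcc2 (−0.53) and Sox6 (−0.69) fell in batch 3 RNA and Specc1 (−0.09) did not pass. Nkd1 (2.25) and Fam171a2 (47.5 to 113 CPM, adjusted p = 0.00085) rose in batch 3 RNA, and Zfp518b (0.54), Phc2 (0.11) and Scoc (−0.01) did not pass. With an interaction term Zfp518b was called in batch 3 (0.53, SE 0.13, adjusted p = 0.0042), and Phc2 and Scoc were not.

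RNA of genes with such promoters differed in the direction of the mark. In batch 3, from the same 4 lines, 75 of 161 genes that gained H3K27me3 were lower and 6 higher in KO (median −0.75, adjusted p = 2.9e-17), and 28 of 68 that lost it were higher and none lower (median 0.49, adjusted p = 8.5e-08). Of 90 genes that lost H3K27ac 45 were lower and 7 higher (median −0.96, adjusted p = 2.4e-10), and of 21 that gained it 8 were higher and 3 lower (median 1.15, adjusted p = 0.037). In batch 1, from other cultures, the same sets gave 95 lower and 31 higher of 169 (median −0.65, adjusted p = 1.2e-06), 49 higher and 10 lower of 78 (0.84, 1.2e-05), 49 lower and 26 higher of 110 (−0.37, 0.013), and 21 higher and 3 lower of 34 (1.24, 0.0083). In batch 1 splits of the libraries, the real one included, gave a p as small in 4 of 10 cases for H3K27me3 gained, 2 for H3K27me3 lost, 5 for H3K27ac lost and 5 for H3K27ac gained. All p are from camera, adjusted over 8 tests. They compare genes and not lines. In batch 3 the sets were chosen by the same split of the same 4 lines. The test there cannot tell the genotype from any other difference between these lines. With an estimated correlation the unadjusted p were 0.019 and 0.03 for H3K27me3 gained in batches 3 and 1, 0.028 and 0.051 for H3K27me3 lost, 0.012 and 0.15 for H3K27ac lost, and 0.44 and 0.18 for H3K27ac gained.

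**Figure D5:**
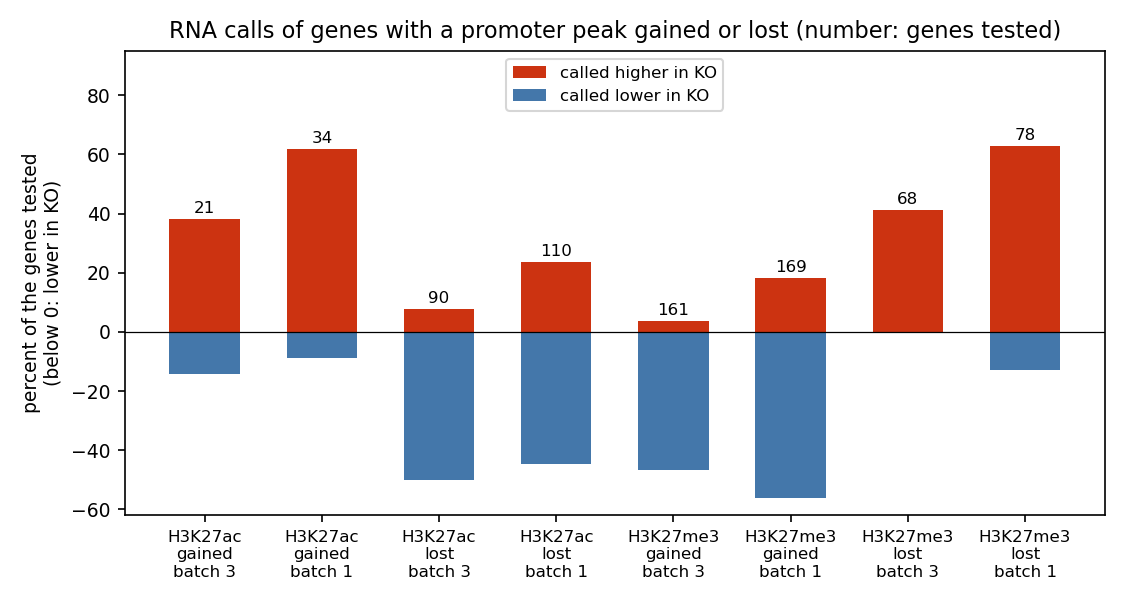
Percent of tested genes called higher (above 0) or lower (below 0) in KO among genes whose promoter gained or lost a peak, per mark and RNA batch, with the number of genes tested above each bar. None of the 68 genes that lost H3K27me3 was called lower in batch 3.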

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

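All tests of this part were chosen before their results were seen, and the 5 genes named for opposite changes were chosen after. The KO effect differed between batches 1 and 3 for 2582 genes by a test of the difference itself (an interaction term in edgeR), and by the batch effects of that same fit 173 of them were called in each batch in opposite directions (76 genes by the separate fits of the batches). The most expressed of these were Sfpq, which encodes a splicing factor (log2 fold change in batch 1 minus batch 3 of 0.56), the nucleolin gene Ncl (−0.76), Luc7l2 (0.65), the imprinted gene Nnat (1.69) and Zfp871 (0.81). In KO libraries of batch 1, 2.12% of fragments lay in loci without a known gene, which the comparisons of genes leave out, against 1.14% in WT.

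The difference between batches could have several sources, and of the tested ones only undeleted cells are argued against. Undeleted cells in the batch 3 KO cultures would set a common floor, yet 71.2% of the 73 genes that fell by more than 3 on the log2 scale in batch 1 fell by more than 2 in batch 3. Sex-linked genes made up 3.99% of the differing genes and 3.65% of all tested genes. The prediction for the sex of the cultures asked for a share that the tested sex-linked genes were too few to reach. It could not decide, and the sex of the cultures stays open. Different assemblies of the 2 batches stay open, since genes whose locus span differed by more than 10% were 1.34 times as frequent among the differing genes (13.6 against 10.1%). A difference between the lines or their culture was not tested and is confounded with batch.

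The larger share of fragments in loci without a known gene in KO of batch 1 was not due to a few loci, since the 10 largest held 14.9% of the excess. Genomic DNA in the KO libraries stays open, with 73.5% of 3690 loci higher in KO. Transcripts running past known genes stay open as well, since loci within 10 kb of a known gene held 6.4 points more of the excess than of the WT fragments. Loss of Mettl14 had support in other cultures, at the loci that could be compared. Of 2166 loci called higher in batch 1 KO, 399 overlapped such a locus of batch 3. In batch 3, 83.2% of these were higher in KO, against 15.7% of 89 loci called lower. The share of all loci without a known gene was 0.47 ± 0.13% in KO and 0.36 ± 0.02% in WT of batch 3, from another assembly. Per library it was 0.56 and 0.38% in KO and 0.38 and 0.35% in WT, so 1 KO library carried the higher mean.

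For the higher RNA of m6A-marked genes in KO, expression level and transcript length as the whole cause are argued against. The median of 0.14 lay above the central 95% of matched lists, which ended at 0.021 with expression matched and at 0.042 with length matched as well. A change that grows with the number of m6A regions may contribute but stays open: genes with 3 or more regions were farther from unmarked genes than genes with 1 region, and on the same side of them, in 7 of 9 bins, where the prediction asked for 8. In the other 2 bins, each with fewer than 20 genes with 3 or more regions, they were farther too, but genes with 1 region lay on the other side of unmarked genes (0.16 against 0.19, and −0.02 against −0.01). Chance could not be excluded for the test of the set, since 7 of 60 splits of the libraries within batches gave a −log10 p as large (3.36 for the real split, 3.78 for the highest other, which kept 2 of 3 KO libraries of batch 1 and 2 of 2 of batch 3 in place).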

How the results depend on the processing

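The alternatives were chosen before the data were examined. Of 2070 values of single genes under alternatives, 2013 had the direction and call of the reported value, 33 were weaker, 4 stronger, 19 moved and 1 reversed, at −0.03 without batch 1. Of 261 values of other results 202 were the same, 16 weaker, 21 stronger and 22 moved.

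At least 1.5-fold was met by 4967 genes for KO against WT over batches, 4999 for KO against Het and 5780 for KO in batch 1. Without batch 1, 3968 were called for KO, and without batch 3, 2 for Het, as with the 2 genotypes alone. DESeq2 called 6 genes for Het over batches and 25 in batch 1. With 1 library left out in turn the counts ran from 7933 to 9262 for KO over batches, 6920 to 8802 for KO against Het, 8771 to 9444 for KO in batch 1, 2079 to 5642 for KO in batch 3, 1 to 3 for Het over batches and 0 to 17 for Het in batch 1. A lone library left in a group is assumed to vary like the other groups. On FPKM with limma the median of all genes shifted by −0.15 for KO against Het, by −0.11 for KO in batch 1 and by −0.1 or less in size for the other comparisons.

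Camera with an estimated correlation called 0 lists for KO and 0 for Het. Fry called 19 and 0, and without batch 3 camera called 7 for KO. Genes with a peak in any m6A list gave p = 0.22 in camera at the preset correlation. For RNA by promoter the p were, with an estimated correlation, 0.44 and 0.18 for H3K27ac gained in batches 3 and 1, 0.15 for H3K27ac lost and 0.051 for H3K27me3 lost in batch 1; with equal numbers of top peaks 0.1 for H3K27ac gained in batch 3; and with promoters of 2.5 kb to each side 0.071 for H3K27ac lost in batch 1.

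Stricter peaks gave gaps of 0.098 for H3K27ac and 0.054 for H3K27me3, 146 H3K27me3 promoters and 52.2% m6A overlap, and 50% reciprocal overlap gave 46.3%. Leaving out 1 line gave 798 to 1037 promoters for H3K27ac and 783 to 1105 for H3K27me3, where fewer lines have to share a state. No paired analysis was possible because each m6A list joins, by its name, 1 IP with 1 input and the RNA columns carry no matching numbers. Settings with batch 2 were not run, since its table is the same as that of batch 1, and Het cannot be tested without batch 1.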

Other observations

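All tests of this part were chosen before the results they measure were seen. For KO against WT over batches chance is argued against, since 1 of 60 splits of the libraries within batches, the real one, called as many as 8594 genes. That is the smallest share these splits can give. The highest other called 4107 and kept all 3 KO libraries of batch 1 in place. For the gene lists of the same comparison chance could not be excluded: 43 of 60 splits called as many lists as the real one, with 4 for the real split and 9 for the highest other, so the number of called lists does not set KO apart.

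For the other comparisons the splits are too few for a share under 0.05. In batch 1, 1 of 10 splits reached the real count for KO against WT (9463 genes, highest other 0) and 1 of 10 for Het against WT (2 genes, highest other 0). Over batches, 1 of 20 reached it for Het against WT (1 gene, highest other 0), 15 of 20 for the Het gene lists (4 lists, highest other 6) and 1 of 20 for KO against Het (7862 genes). The highest other for KO against Het, 7245 genes, exchanged all KO and Het libraries of batch 1 and so follows the genotypes. For RNA of genes with gained or lost promoter marks in batch 1, the −log10 p of the real split and of the highest other were 2.21 and 4.39 for H3K27ac gained (5 of 10 splits as large), 1.95 and 5.32 for H3K27ac lost (5 of 10), 6.21 and 8.77 for H3K27me3 gained (4 of 10) and 5.14 and 5.21 for H3K27me3 lost (2 of 10).

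A partial KO change in Het had no support in this test but stays open. The prediction against it asked for a median of the higher genes at or below that of the lower genes. Genes called higher in batch 3 KO had a median log2 fold change in Het of 0.009 and genes called lower one of −0.006, a difference of 0.015. Neither set passed camera (adjusted p = 0.5 for each).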
